A study of Arabidopsis thaliana with 21 samples.

How the data were processed

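RNA of 7-day-old Arabidopsis thaliana seedlings was sequenced in 21 libraries, 3 replicates in each of 7 groups. The groups were WT and hy5 in growth light, WT and hy5 after 2 h of high light, and the HY5-GFP lines K87K, K87Q and K87R in growth light. The labels describe poly-T selection of mRNA, and they state no strand setting. They place K87K and K87Q in one hy5 allele and K87R in another, and give no allele for the samples called hy5. Samples were joined to their columns by the names in the labels, with 0 columns left unmatched. No library was left out of the planned analysis.

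The deposited values are raw counts per gene. Per the submitters' processing notes, fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with build TAIR10, with no role given for each tool. The values were checked to be whole numbers from 0 with a different total in each library. The table held 32833 genes, of which 32548 carried a locus identifier of the reference annotation and 32532 the same start and end. Gene symbols (10933 genes) came from the table or the reference. The table held 133 plastid and 152 mitochondrial genes and 27628 protein-coding genes. A count per gene does not tell the HY5-GFP transgene from endogenous HY5.

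Depth per library is given in the report. CPM are counts scaled by the TMM library sizes, so that 1 CPM is about 15 counts at the median depth. Values after ± are SD over 3 libraries for CPM and for log2 fold changes the SE of the fit, the fold change over the root of F.

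Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (20234 genes tested), TMM scaling, robust dispersion and quasi-likelihood F tests on 1 fit of all 21 libraries with a mean per group. The 12 planned contrasts were high against growth light in WT and in hy5, their interaction, hy5 against WT in each light, each line against hy5, K87Q and K87R against K87K, K87Q against K87R, and K87K against WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene is from edgeR, and every adjusted p of a list or set is from camera in limma 3.58.1, unless DESeq2 (1.42.0) is named. The 12 contrasts share libraries and were not adjusted for their number.

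Gene lists, contrasts, alternatives and the rule for named genes were fixed before the data were examined. The 22 lists held 406 genes, 405 of them in the table, and covered the flavonoid and phenylpropanoid pathways, light stress, photosynthesis, growth, hormones, the clock, acetylation enzymes, sugar and nitrate status and tissue markers. Each list was tested in each contrast with camera on log CPM (prior count 2) with an inter-gene correlation of 0.01. Camera compares the list with the other genes, and its adjusted p is over the lists of 1 contrast. A list's direction is that of its camera test, which can differ from the sign of its median where members move both ways. Lists not described in the report for a contrast were not called there by camera.

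The text names HY5 in every contrast, and for each list described 2 to 4 members with the smallest adjusted p and any member given as not passing. It also names genes from the 8 largest positive and 8 largest negative log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 100 counts in the higher group, a symbol, and every library of one group above every library of the other. For the interaction the separation of libraries was not asked for. Genes named for hy5 against WT were followed in the lines, where the text gives only some of them. Chance separates 3 against 3 libraries in 10% of genes. A fold against a group at 0 counts was computed against a floor of 3 counts over the group, and a group with 1 to 3 counts is given as a ratio with its 95% counting interval. Floors and these intervals cover counting error only, not the spread between replicates.

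Genes called in hy5 against WT in high light (466 lower, 170 higher) and in WT high against growth light were followed as sets in the lines with camera and a median. The overlap of the light responses in WT and hy5 was counted beside the product of their shares. Pairing by replicate number was checked by correlating, across genes, the deviations of like-numbered libraries from their group means. These r were 0.159 to 0.483 for hy5 and WT in high light and -0.126 to 0.134 in the other contrasts. Replicate numbers were read as pairs in high light alone, a choice that these r do not settle. Deviations within a group sum to 0, so the shared shift of the replicate 3 libraries could raise every r there. Column names do not settle the pairing either. In high light the columns of WT replicate 2 and hy5 replicate 1 have names made from the genotype, as do the replicate 1 columns in growth light. The other high-light columns have names of a numbered series. WT replicate 2 and hy5 replicate 1 also had the highest Spearman correlation between the genotypes in high light (0.915). Libraries best matched by their own number counted 4 in high light. They counted 6 in hy5 against WT in growth light, K87K against hy5 and K87K against WT. Outliers within groups were not tested, since the test needs 4 libraries.

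The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With 1 spread for all libraries, 2-fold changes were found in 5% (WT high against growth light), 2% (hy5 against WT in high light), 1% (hy5 against WT in growth light), 3% (K87Q against K87K) and 4% (K87Q against K87R). The shares for 4-fold changes were 53%, 53%, 54%, 55% and 55%, and false calls were 1 of 60, 1 of 56, 2 of 57, 4 of 64 and 3 of 63. The real spread differed by light: the biological coefficient of variation was 0.431 over 21 libraries and 0.189 over the 15 growth-light libraries.

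With separate simulated spreads the fit over 21 libraries found 9%, 23%, 0%, 0% and 1% of 2-fold and 59%, 69%, 41%, 44% and 48% of 4-fold changes in the same order, with 135 false calls of 204, 1660 of 1763, 0 of 41, 0 of 44 and 0 of 49. With the spread from the compared groups alone, 0 calls were made in WT high against growth light and 0 in hy5 against WT in high light. From growth-light libraries alone, 66%, 60% and 66% of 2-fold and 91%, 92% and 93% of 4-fold changes were found in the last 3 contrasts, with 5 false calls of 176, 10 of 176 and 11 of 184. A simulated list lowered 2-fold was found in every case, and an unchanged list gave p from 0.0379 to 0.640 (simulated, not exact). Genes and libraries were simulated independently of each other. The simulation therefore tested neither the preset correlation of camera nor the effect of a shift shared by libraries.

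The alternatives planned were RLE scaling, no filter on low counts (25415 genes), DESeq2, the compared groups alone, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated correlation, and leaving out each library. Added after seeing the data were fits without the high-light replicate 3 libraries of WT and hy5, the 15 growth-light libraries alone, the 6 high-light libraries with a block, and an estimated correlation for the sets. RLE moved the median log2 fold change most in WT high against growth light (-0.0487). Tables and figures were made with Python 3.11.15 and pandas 2.3.3.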

Results

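The data were RNA-seq counts of genes from 7-day-old Arabidopsis thaliana seedlings in 21 libraries, 3 biological replicates in each of 7 groups. Wild type (WT) and the hy5 mutant, which lacks a functional HY5 gene, were sampled in growth light and after 2 h of high light, at photon fluxes of 100 and 500 µmol m-2 s-1. HY5 is a bZIP transcription factor that acts downstream of photoreceptors and promotes photomorphogenesis. The other 3 groups, sampled in growth light alone, were hy5 lines that expressed HY5-GFP from a constitutive promoter. The protein carried the original lysine (K87K), a glutamine, often used to mimic an acetylated lysine (K87Q), or an arginine, which cannot be acetylated (K87R). The labels place K87K and K87Q in one hy5 allele and K87R in another. Line and substitution changed together, and the allele changed too where K87R was compared with K87K or K87Q. No allele was given for the samples called hy5.

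Library depth ranged from 7283290 to 22101539 counts, with a median of 14815169. For replicates 1, 2 and 3, WT had 17143679, 13545719 and 18030809 counts in growth light and 20003295, 12918249 and 20156211 in high light. The hy5 mutant had 19811935, 14208669 and 14432305 in growth light and 19690010, 14109984 and 17518039 in high light. K87K had 14815169, 12686313 and 13010827, K87Q had 22101539, 15265763 and 16240680, and K87R had 7283290, 13856897 and 12868961. Across genes, Spearman correlations between replicates were 0.968 to 0.988 in the growth-light groups, against 0.743 to 0.949 in WT and 0.717 to 0.926 in hy5 in high light. The high-light replicate 3 libraries of WT and hy5 stood apart from replicates 1 and 2, and plastid genes held 6.52% and 7.30% of their counts, against 4.15% or less in every other library.

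**Figure D1:**
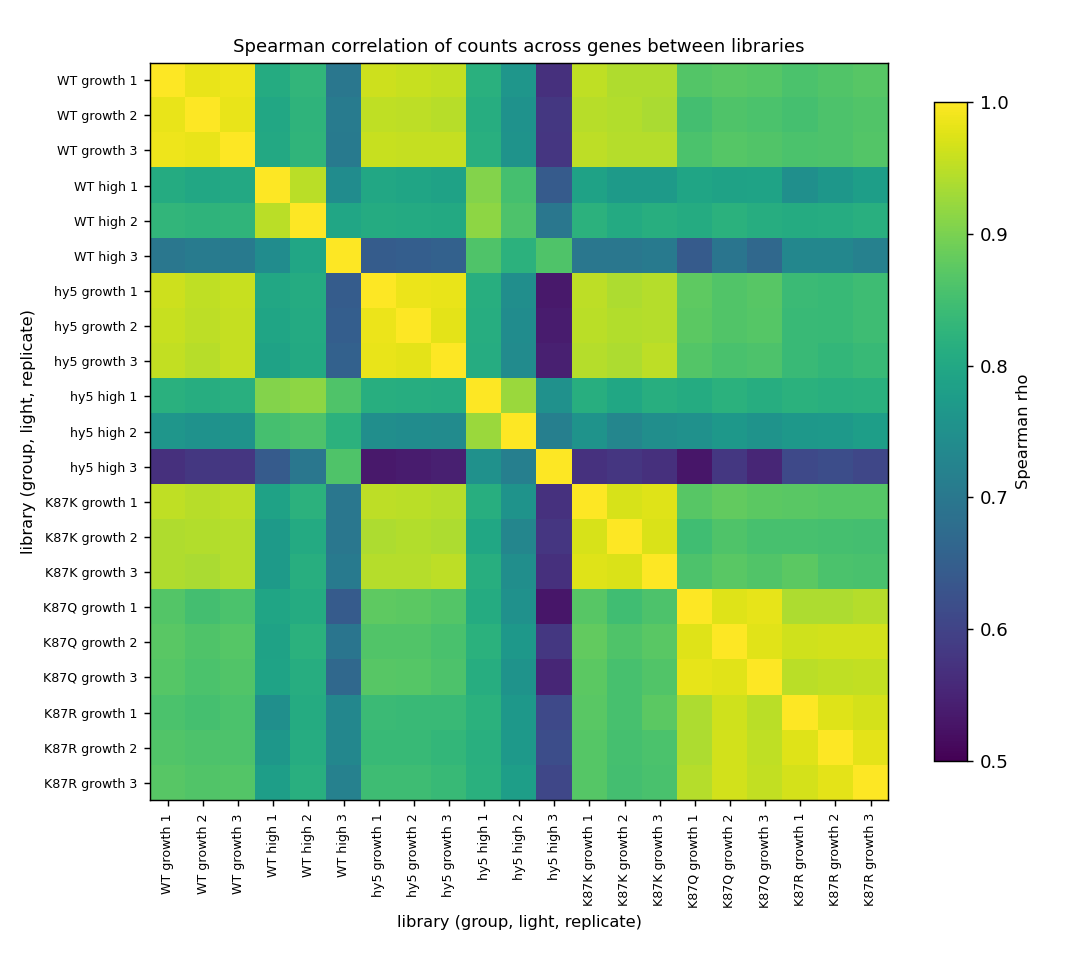
Spearman correlation of counts across genes between all 21 libraries, named by group, light and replicate. Pairs within the growth-light groups lie between 0.968 and 0.988, and the replicate 3 libraries of both high-light groups lie apart from the rest.

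HY5 (AT5G11260, chromosome 5, 3593335 to 3595073 in TAIR10) was measured in every library before the other genes. In growth light WT held 8.64 ± 1.47 CPM (counts scaled by library size, SD, n = 3) and hy5 held 0.552 ± 0.612, from 1, 4 and 14 counts. In high light WT held 66.8 ± 34.8 and hy5 0.276 ± 0.253, from 5, 0 and 12 counts. The HY5-GFP lines held 284 ± 72.1 (K87K), 248 ± 19.2 (K87Q) and 344 ± 58.8 CPM (K87R), and the counts do not tell the transgene from the endogenous gene. Without TMM scaling the means were 278 (K87K), 309.8 (K87Q) and 528 CPM (K87R), with K87Q above K87K. HY5 rose in WT under high light by 2.95 ± 0.55 on the log2 scale (SE, adjusted p = 6.3e-04; all 3 libraries above all 3). In the hy5 mutant the light effect was -0.72 ± 0.73 (adjusted p = 0.470), and the interaction was -3.66 ± 0.91 (adjusted p = 0.131). HY5 was lower in hy5 than in WT by log2 -4.02 ± 0.64 in growth light (adjusted p = 0.0089) and -7.68 ± 0.72 in high light (adjusted p = 6.3e-06). K87K exceeded hy5 by 9.06 ± 0.75 and WT by 5.04 ± 0.61 (adjusted p = 1.8e-04), and K87Q and K87R exceeded hy5 by 8.86 ± 0.75 (adjusted p = 3.0e-07) and 9.33 ± 0.76 (adjusted p = 2.1e-07). No difference between the lines passed the test: K87Q minus K87K was -0.20 ± 0.51 (adjusted p = 0.845), K87R minus K87K was 0.27 ± 0.51 (adjusted p = 0.763) and K87Q minus K87R was -0.47 ± 0.51 (adjusted p = 0.829).

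**Figure D2:**
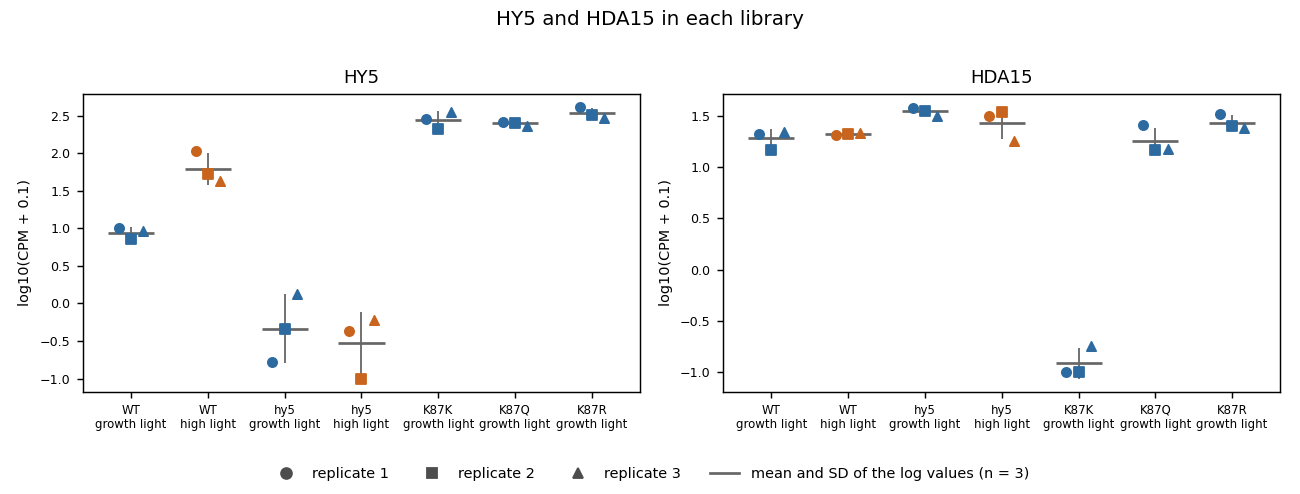
HY5 and HDA15 in each library, as log10 of CPM plus 0.1, by group and light. Points are libraries, bars the mean and SD of the log values (n = 3). HY5 was lowest in hy5 and highest in the HY5-GFP lines, and HDA15 held 0, 0 and 1 counts in K87K.

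The response of WT to high light was asked first. Heat-shock genes rose most. The small heat-shock protein genes HSP22 and HSP21 had 0 counts in growth light and were at least 38302-fold and at least 16649-fold higher in high light, and HSP70B, a cytosolic chaperone, rose by log2 11.01 ± 0.95 (adjusted p = 1.5e-07). APX2, a cytosolic ascorbate peroxidase induced by excess light, was higher by a ratio of 3558 (counting interval 1217 to 17257). The expansin genes EXPA1 (log2 -4.77 ± 0.63) and EXPA8 (-5.50 ± 1.04) and the pectin methylesterase gene PME5 (-6.53 ± 0.67) fell. ESE3, an AP2/ERF transcription factor, was lower by a ratio of 206 (70.1 to 1001). Unless stated otherwise, all 3 libraries of one group lay above all 3 of the other for each gene said to rise or fall.

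By list, all 28 measured heat shock response genes rose in WT (28 adjusted over the list alone, median log2 9.48, camera adjusted p = 2.5e-44), among them HSP17.6II (10.34 ± 0.61, adjusted p = 3.5e-09) and HSA32 (5.68 ± 0.35). Of 33 elongation growth, shade and auxin response genes 16 fell and 0 rose (20 adjusted over the list alone, median -1.87, adjusted p = 1.8e-07). They included PIF5, a growth-promoting bHLH factor (-2.32 ± 0.27), and BAS1, a brassinosteroid-inactivating enzyme (-2.44 ± 0.33). Of 23 circadian clock genes 13 rose and 4 fell (14 and 4 adjusted over the list alone, median 1.67, adjusted p = 0.0052), led by PRR5 (3.47 ± 0.32), COR27 (5.53 ± 0.55) and LUX (2.62 ± 0.29). Of 10 cold and abscisic acid response genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 3.29, adjusted p = 0.0086), led by the stress genes RD29A (4.90 ± 0.49) and KIN1 (6.21 ± 0.94). Of 15 root markers 7 fell (7 adjusted over the list alone, median -1.22, adjusted p = 0.0086), led by BGLU23 (-2.97 ± 0.40) and the iron transporter gene IRT1 (-4.45 ± 0.97). The clock list (12 higher and 7 lower, median 0.81) and the root list (median -1.40) were no longer called without the high-light replicate 3 libraries, each at adjusted p = 0.082.

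Camera calls were made with a preset correlation between genes, and 74 of the list calls described for the 12 comparisons were lost when it was estimated from the data. In the light comparisons heat shock held in WT and in hy5, and elongation growth in hy5. Photoprotection, HY5-COP1 photomorphogenesis, elongation growth, carbon starvation, salicylate and jasmonate defence, and seed storage held in K87Q and in K87R against hy5 and in K87R against K87K. In K87Q against K87K, HY5-COP1 photomorphogenesis, elongation growth, carbon starvation and seed storage held, and carbon starvation held in K87K against WT.

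Flavonoid and photoprotection genes were called as genes but not as lists. Of 16 flavonoid and anthocyanin biosynthesis genes 7 rose and 0 fell (8 adjusted over the list alone, median 1.42, adjusted p = 0.075). The flavonol synthase gene FLS1 rose by 4.39 ± 0.53 (adjusted p = 7.2e-06), from 15.9 ± 1.81 to 335 ± 230 CPM, and the glycosyltransferase gene UGT78D2 by 2.49 ± 0.45. MYB12, the activator of flavonol genes, rose by 5.14 ± 0.57. Of 24 photoprotection genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.18). Both lists were called without the high-light replicate 3 libraries (adjusted p = 1.7e-04 and 0.0065). The plastid chaperone gene CLPB3 rose by 4.72 ± 0.58 and ELIP1, an early light-induced protein of the thylakoid, by 8.26 ± 1.38. ELIP1 held 3401 and 1278 CPM in replicates 1 and 2 and 49.3 in replicate 3, against 3.74 to 5.98 in growth light.

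In WT 2828 genes rose and 2191 fell in high light, 5019 in all. Without the high-light replicate 3 library of WT and hy5, a choice made after seeing the data, 9513 passed, among them 4741 of the 5019. The count was 2906 with the spread taken from the 6 libraries alone, and on simulated data with separate spreads for each light the fit over 21 libraries made 135 false calls of 204, which limits single calls here. Few genes were changed in the simulation, so that share does not measure the share of false calls among the real ones.

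The same light step was taken in hy5. The heat-shock genes again rose most: HSP23.6, a mitochondrial small heat-shock protein gene, rose by log2 15.58 ± 1.104, HSFA2, a heat-stress transcription factor, by 12.57 ± 0.99, and HSP70B by 12.34 ± 0.99. HSP22 was higher by a ratio of 72481 (20065 to 598503). EXPA1 (log2 -6.63 ± 0.68), EXPA8 (-7.23 ± 1.13) and WRKY22, a WRKY transcription factor gene (-7.20 ± 0.88), fell, and the auxin-response gene SAUR65 was lower by a ratio of 276 (75.8 to 2283).

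By list in hy5, all 28 heat shock response genes rose (28 adjusted over the list alone, median 11.04, adjusted p = 1.5e-37). There 21 of 33 elongation growth, shade and auxin response genes fell with 0 higher (1 higher and 23 lower adjusted over the list alone, median -2.36, adjusted p = 1.5e-08). The clock list held 12 higher and 2 lower of 23 (13 and 2 adjusted over the list alone, median 1.04, adjusted p = 0.0024), with PRR5 at 3.13 ± 0.31 and COR27 at 4.90 ± 0.54. Of 17 general phenylpropanoid and monolignol genes 11 fell and 1 rose, with the same counts adjusted over the list alone (median -1.47, adjusted p = 0.0024). The ligase genes 4CL2 (-2.32 ± 0.30) and 4CL1 (-1.47 ± 0.25) fell, and CAD5, a cinnamyl alcohol dehydrogenase gene, rose by 2.101 ± 0.33. Of 15 root markers 10 fell and 1 rose (the same adjusted over the list alone, median -2.68, adjusted p = 5.7e-04), led by the root-hair wall genes LRX1 (-5.11 ± 0.65) and COBL9 (-6.26 ± 0.90). Of 10 cold and abscisic acid response genes 6 rose (6 adjusted over the list alone, median 3.91, or 3.64 with members at their bound, adjusted p = 0.0047), RD29A by 6.76 ± 0.54.

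Photosynthesis lists were lower in hy5 under high light, in libraries that include the replicate 3 library with 7.30% plastid counts. Of 33 photosystem, electron transport and Rubisco genes 5 fell and 1 rose (4 and 1 adjusted over the list alone, median -0.92, adjusted p = 0.0024), with the ferredoxin reductase gene FNR2 higher by 1.48 ± 0.31 and the ATP synthase gene ATPD at -1.34 ± 0.37. The light-harvesting complex list had 0 of 20 genes passing by edgeR and 0 adjusted over the list alone (median -0.97, adjusted p = 0.041), and its lowest adjusted p was that of LHCB2.2 (-1.71 ± 0.74, adjusted p = 0.079). Of 15 carbon starvation and sugar status genes 5 fell and 1 rose (the same adjusted over the list alone, median -0.64, adjusted p = 0.041), among them the trehalose-phosphate synthase family genes TPS11 (-3.07 ± 0.24) and TPS8 (-2.53 ± 0.29). The light-harvesting list (median -0.43, adjusted p = 0.28) and the carbon starvation list (median -0.57, adjusted p = 0.058) were no longer called without the high-light replicate 3 libraries.

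In hy5 3817 genes rose and 3573 fell, 7390 in all, and 6624 of these passed among the 9674 called without the high-light replicate 3 libraries. The count was 3097 with the spread taken from the 6 libraries. Between genotypes, 2061 genes rose in both light comparisons (533 by chance), 1575 fell in both (387 by chance) and 12 were called in opposite directions, with no library shared. Without the high-light replicate 3 libraries 462 genes had opposite calls and 2650 fell in both. Opposite calls numbered 247 without WT high-light replicate 3, 47 without hy5 high-light replicate 1, 28 without hy5 high-light replicate 3, 21 by DESeq2, and 5 to 13 without any other single library.

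Whether the light response differed between hy5 and WT was tested by the interaction, in which 5 genes were higher and 13 lower. FLS1 had an interaction of log2 -3.88 ± 0.71 (adjusted p = 0.035): it held 335 ± 230 CPM in WT and 3.82 ± 1.07 in hy5 in high light, against 15.9 ± 1.81 and 2.66 ± 0.948 in growth light. The ligase gene 4CL3 had -5.47 ± 0.84 (adjusted p = 0.017) and RWP1, an acyltransferase gene of suberin synthesis, -3.72 ± 0.46 (adjusted p = 0.0012). BBX16, a B-box factor gene, had the smallest adjusted p (3.49 ± 0.35, adjusted p = 9.4e-05) and moved from 24.96 ± 1.77 to 133 ± 29.3 CPM in hy5 while WT held 20.1 ± 3.13 in high light. The others named by the rule were BGLU18 (1.98 ± 0.31), ACS6, an ethylene synthesis gene (2.52 ± 0.47), UMAMIT33 (-3.71 ± 0.64), the nitrate transporter gene NRT1.8 (-4.18 ± 0.78) and HCF152, a plastid RNA-binding protein gene (-2.18 ± 0.40). With the replicate number as a block, NRT1.8 (adjusted p = 0.063) and HCF152 (adjusted p = 0.053) no longer passed.

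Of the lists, flavonoid and anthocyanin biosynthesis had 1 lower gene of 16 in the interaction (1 higher and 9 lower adjusted over the list alone, median -1.66, adjusted p = 9.0e-04). General phenylpropanoid and monolignol genes had 1 lower of 17 (4 lower adjusted over the list alone, median -0.79, adjusted p = 9.0e-04). Heat shock response genes leaned higher (0 called, and 1 higher and 1 lower adjusted over the list alone, median 1.26, adjusted p = 1.2e-04). Flavonoid regulators (adjusted p = 0.016, 0 adjusted over the list alone) and the elongation list (adjusted p = 0.013, 3 lower adjusted over the list alone) were also called. So were root markers (adjusted p = 0.048, 4 lower adjusted over the list alone) and genes known to differ between Col and other accessions (adjusted p = 0.016, 2 higher adjusted over the list alone). With an estimated correlation 0 of these 7 lists were called (adjusted p = 0.38 for 6 of them and 0.51 for root markers). When the high-light replicate 3 libraries were left out, 11 flavonoid and 10 phenylpropanoid genes were lower, and 17 heat shock genes were higher and 1 lower. In that fit, chosen after seeing the data, 3 lists passed with an estimated correlation: flavonoid (adjusted p = 0.0034), phenylpropanoid (adjusted p = 0.014) and genes known to differ between accessions (adjusted p = 0.034). The count of 18 genes was 361 by DESeq2, 1 (BBX16) with the spread from the 12 libraries and 5153 without the high-light replicate 3 libraries. It ran from 2 to 3382 when 1 library was left out: 3382 without WT high-light replicate 3, 1174 without hy5 high-light replicate 1, 85 without hy5 high-light replicate 3, 7 and 9 without WT high-light replicates 2 and 1, and 2 to 4 without any one growth-light library.

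In growth light, hy5 was compared with WT. GRP5, a glycine-rich protein gene, was higher in hy5 (log2 3.77 ± 0.60, 10.3 ± 0.0974 against 0.742 ± 0.270 CPM). The pectin methylesterase gene ATPMEPCRD (3.52 ± 0.51), KAK, a ubiquitin ligase gene of trichome development (1.85 ± 0.36), and the glyoxalase gene GLYI4 (1.80 ± 0.29) were higher as well. Besides HY5, the lower genes included GRP9, another glycine-rich protein gene (-4.14 ± 0.59), PELPK1, a cell-wall protein gene (-3.08 ± 0.57), FLS1 (-2.57 ± 0.51, adjusted p = 0.043), CYP79F1, an aliphatic glucosinolate synthesis gene (-2.37 ± 0.42), and the annexin gene ANNAT1 (-1.74 ± 0.28). MYB12 was lower by a ratio of 86.1 (counting interval 15.1 to 3433, adjusted p = 0.0085), with 0, 0 and 1 counts in hy5 and 37, 29 and 33 in WT.

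Of 16 flavonoid and anthocyanin biosynthesis genes 1 fell in growth light (4 adjusted over the list alone, median -0.58, adjusted p = 0.020). The chalcone synthase gene CHS held 8.05 ± 1.102 CPM in hy5 and 145 ± 3.17 in WT, with no overlap (log2 -4.17 ± 1.14), but its adjusted p was 0.15. The carbon starvation and sugar status list leaned higher with 0 of 15 genes passing by edgeR and 0 adjusted over the list alone (median 0.52, adjusted p = 0.020), DIN10 at 0.97 ± 0.37 (adjusted p = 0.38). The elongation list likewise had 0 of 33 passing and 0 adjusted over the list alone (median 0.36, adjusted p = 0.033), BAS1 at 1.03 ± 0.31 (adjusted p = 0.20). In all 23 genes were higher and 21 lower in hy5, 44 together. The count was 346 by DESeq2, 6863 with the spread from the 6 libraries, 4618 from the 15 growth-light libraries and 2125 without the high-light replicate 3 libraries, and 3 to 10 without any one of the 6 libraries.

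In high light hy5 was compared with WT as well. MYB12 held 125, 68.1 and 46.6 CPM in the WT libraries and at most 1 count in a hy5 library, lower by a ratio of 3553 (637 to 140379). CHS (log2 -8.77 ± 1.397, adjusted p = 0.0019), FLS1 (-6.45 ± 0.59, adjusted p = 6.3e-06), 4CL3 (-7.25 ± 0.70), the glycosyltransferase gene UGT84A1 (-4.63 ± 1.06) and RWP1 (-4.43 ± 0.37) were lower in hy5. LPR1, a ferroxidase gene of the root phosphate response, was lower by a ratio of 127 (43.0 to 617). BBX16 (2.72 ± 0.26), HSFA7B, a heat-stress factor gene (3.16 ± 0.58), and GRP5 (2.93 ± 0.58) were higher in hy5.

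Of 16 flavonoid and anthocyanin biosynthesis genes 8 were lower in hy5 in high light and 0 higher (11 adjusted over the list alone, median -2.91, adjusted p = 3.9e-08), UGT84A2 at -3.85 ± 0.43. With an estimated correlation neither this list (adjusted p = 0.35) nor the 5 other lists called here (adjusted p = 0.41 to 0.74) passed. Of 17 general phenylpropanoid and monolignol genes 6 were lower (7 adjusted over the list alone, median -1.06, adjusted p = 8.0e-06), among them PAL1, the entry enzyme of the pathway (-2.17 ± 0.38). Of 11 flavonoid regulators 2 were lower (3 adjusted over the list alone, median -1.07, adjusted p = 8.6e-04). Heat shock response genes leaned higher in hy5 with 1 of 28 called (1 adjusted over the list alone, median 0.68, adjusted p = 2.1e-04). Antioxidant enzymes had 1 lower gene of 20, the glutathione peroxidase gene GPX7 at -2.20 ± 0.41 (2 adjusted over the list alone, adjusted p = 0.030, or 0.091 without the high-light replicate 3 libraries). The photosystem list had 0 of 33 by edgeR (0 adjusted over the list alone, median -0.54, adjusted p = 0.038). Of lists not called, photoprotection held ELIP2 (-5.70 ± 1.22) and ELIP1 (-4.65 ± 1.17, adjusted p = 0.036), both with overlapping libraries, and the clock held ELF4 (-4.39 ± 0.74) and TOC1 (-1.02 ± 0.26, adjusted p = 0.061 with the replicate number as a block). The HY5-COP1 photomorphogenesis and UV-B list held HFR1, a bHLH factor gene of light signalling (-2.52 ± 0.32), and RUP1 (-5.02 ± 1.02, overlapping).

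Together 170 genes were higher and 466 lower in hy5 in high light, 636 in all, against 1653 by DESeq2, 1 (MYB12) with the spread from the 6 libraries, and 6117 without the high-light replicate 3 libraries, among them 610 of the 636. Deviations of like-numbered libraries correlated across genotypes in high light (r across genes 0.381, 0.159 and 0.483), which the shift of the replicate 3 libraries alone could give. By the form of their column names WT replicate 2 would go with hy5 replicate 1, so pairing by number is not certain. With the replicate number as a block 476 genes passed over 21 libraries and 29 over the 6 libraries, 28 of them lower and including MYB12 (block adjusted p = 1.6e-04), CHS, FLS1, 4CL3 and LPR1. The count was 4737 without WT replicate 3, 2417 without hy5 replicate 1, 1318 without hy5 replicate 3, 313 without WT replicate 1 and 237 without WT replicate 2. On simulated data with separate spreads 1660 of 1763 calls were false. That shows that the fit over 21 libraries can make false calls when spreads differ by light, but not their share among the 636. Few genes were changed in the simulation, and its libraries varied independently. The real replicate 3 libraries of both genotypes shared a shift, which was not simulated, and the simulation made more calls than the 636 found.

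**Figure D3:**
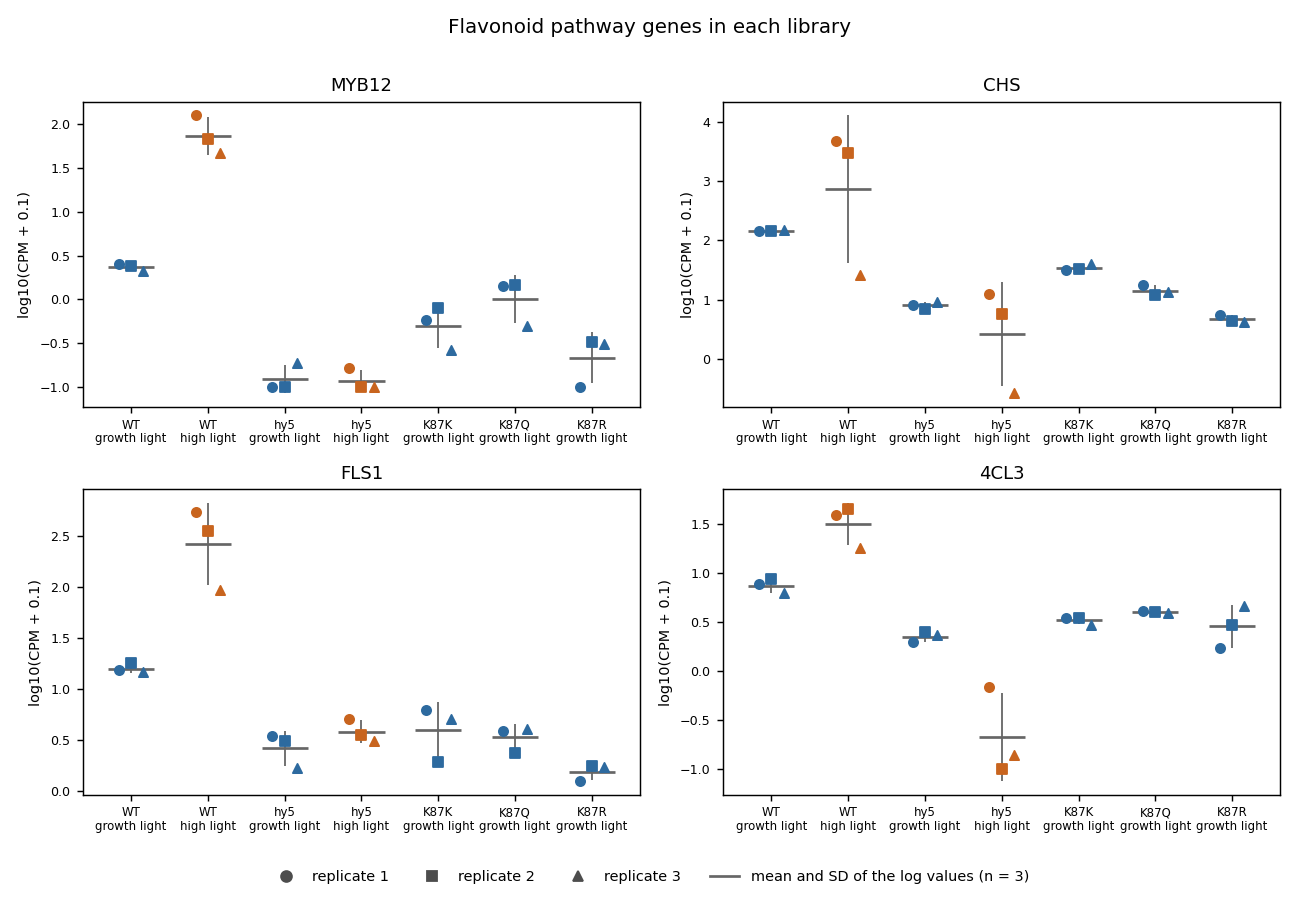
MYB12, CHS, FLS1 and 4CL3 in each library, as log10 of CPM plus 0.1, by group and light. Points are libraries, bars the mean and SD of the log values (n = 3). In high light every WT library lies above every hy5 library, and the WT replicate 3 library is the lowest of its group.

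K87K was compared with hy5 and with WT to ask what the unsubstituted HY5-GFP changed. HDA15 (AT3G18520, chromosome 3, 6361159 to 6365705), which encodes a histone deacetylase, held 0, 0 and 1 counts in K87K. It was lower by a ratio of 783 (140 to 30978) against WT, at 19.3 ± 3.99 CPM, and of 1407 (252 to 55614) against hy5, at 35.0 ± 3.20 CPM. Against hy5, BSU1, a phosphatase gene of brassinosteroid signalling (3.89 ± 0.45), ABC1 (2.72 ± 0.27), the immune receptor gene ADR1 (2.67 ± 0.38) and GPX7 (2.39 ± 0.41) were higher. The autophagy gene ATG18G (-3.38 ± 0.50), BCAT4 (-3.09 ± 0.61), IPMI1 (-3.01 ± 0.64), MAM1 (-2.44 ± 0.35) and CYP83A1 (-2.39 ± 0.39) were lower. The last 4 encode enzymes of methionine-derived glucosinolate synthesis. Against WT, BSU1 (5.35 ± 0.49), the extensin-like gene LRX3 (3.04 ± 0.69), MPL1 (2.59 ± 0.37) and HUA2 (2.27 ± 0.44) were higher, and CYP79F1 (-6.01 ± 0.53), BCAT4 (-4.63 ± 0.64), MAM1 (-3.96 ± 0.37), IPMI1 (-3.65 ± 0.65) and ATG18G (-3.31 ± 0.50) were lower.

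Against hy5 no list passed by camera; among genes known to differ between Col and other accessions MAM1 fell and ESM1, a modifier of glucosinolate breakdown, rose (2.25 ± 0.48), 1 each way of 5 measured (2 each way adjusted over the list alone, adjusted p = 0.85). Against WT the carbon starvation and sugar status list was higher, 2 of 15 genes rising (5 adjusted over the list alone, median 0.77, adjusted p = 6.1e-05), TPS11 by 1.18 ± 0.22 and TPS9 by 1.13 ± 0.24. Heat shock response genes were lower (1 of 28, and 2 adjusted over the list alone, median -0.58, adjusted p = 8.1e-04), with HSFB2A at -2.16 ± 0.34. Photoprotection was also lower (1 of 24, and 1 adjusted over the list alone, median -0.45, adjusted p = 0.0072), with the tocopherol gene VTE4 at -1.65 ± 0.38, as was the photosystem list (0 of 33, and 0 adjusted over the list alone, median -0.45, adjusted p = 0.020).

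Of genes named in the hy5 comparisons, GLYI4 fell (-1.48 ± 0.29, adjusted p = 0.017) and GRP9 rose (3.16 ± 0.57, adjusted p = 0.010) in K87K against hy5, each opposite to its change in hy5 against WT, which shares the hy5 libraries. CYP79F1 fell further (-3.64 ± 0.50, adjusted p = 0.0012). FLS1 (0.70 ± 0.50, adjusted p = 0.67), CHS (2.11 ± 1.05, adjusted p = 0.44) and MYB12 (ratio 17.3, counting interval 2.72 to 719, from 18 and 1 counts, adjusted p = 0.13) did not pass. Neither did 4CL3 (0.57 ± 0.53, adjusted p = 0.78) or PAL1 (0.29 ± 0.36, adjusted p = 0.85). CHS held 31.1 to 40.1 CPM in K87K against 6.91 to 9.11 in hy5 and 142 to 147 in WT. K87K differed from hy5 in 89 genes higher and 81 lower, 170 in all (605 by DESeq2, 5497 with the spread from the 6 libraries and also from the 15 growth-light libraries, 2956 without the high-light replicate 3 libraries, 37 to 57 without any one of the 6 libraries). It differed from WT in 124 higher and 97 lower, 221 in all (753 by DESeq2, 5049 from the 6 libraries, 5036 from the 15 growth-light libraries, 2740 without the high-light replicate 3 libraries, 42 to 73 without any one of the 6 libraries).

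K87Q and K87R were then each compared with hy5. Plant defensin genes were among the highest: PDF1.3 had 0 counts in hy5 and was at least 341-fold higher in K87Q and at least 299-fold higher in K87R, and PDF1.2c was at least 178-fold and at least 168-fold higher. COR15B, a cold-regulated gene, rose by log2 9.12 ± 1.26 and 9.47 ± 1.27, and the seed storage gene CRA1 was higher in K87Q by a ratio of 763 (137 to 30176). The antenna gene LHCB2.3 fell (-7.22 ± 1.36 and -7.67 ± 1.39), from 2126 ± 87.5 CPM to 14.3 ± 1.31 and 10.5 ± 1.94. The extensin gene EXT12 (-5.21 ± 0.62 and -5.94 ± 0.66) and the gene G3Pp2 (-6.29 ± 0.88 and -7.16 ± 0.96) also fell.

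Lists of photosynthesis were lower than in hy5 in both lines. The share of counts in plastid genes was 0.119 to 0.187% in K87Q and 0.104, 0.125 and 1.41% in K87R. It was 0.649 to 4.15% in hy5 and 0.511 to 3.91% in K87K, with K87R replicate 1 inside the range of hy5 and K87K. After poly-T selection this share was not read as plastid gene expression, and it ran from 0.0442 to 6.52% within WT in high light. Photoprotection had 15 lower of 24 in K87Q (2 higher and 17 lower adjusted over the list alone, median -1.46, adjusted p = 5.9e-08) and 16 in K87R (18 adjusted over the list alone, median -1.94, adjusted p = 2.5e-08). Among them was SIG5, a plastid sigma factor gene, at -3.38 ± 0.39 and -2.70 ± 0.38. Chlorophyll biosynthesis had 11 lower and 1 higher of 28 in each (12 and 2, and 14 and 1, adjusted over the list alone, medians -0.87 and -0.93, adjusted p = 2.1e-05 and 7.5e-06), with HEMA1, of tetrapyrrole synthesis, at -3.11 ± 0.27 and -2.63 ± 0.27. The photosystem list had 9 and 14 lower of 33 (10 lower, and 23 lower and 1 higher, adjusted over the list alone, medians -1.50 and -1.87, adjusted p = 2.0e-07 and 3.5e-08). The light-harvesting complex list had 6 and 8 lower of 20 (8 and 13 adjusted over the list alone, medians -1.74 and -2.35, adjusted p = 3.3e-04 and 1.7e-05). HY5-COP1 photomorphogenesis and UV-B genes had 7 lower and 2 higher of 21 in each (9 and 3, and 7 and 2, adjusted over the list alone, medians -0.79 and -0.56, adjusted p = 0.0031 and 0.0048). The B-box genes BBX24 and BBX25 were among them, BBX24 at -1.85 ± 0.26 and -2.05 ± 0.26 and BBX25 at -2.80 ± 0.40 and -2.77 ± 0.40.

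Growth and sugar-status lists were lower as well. Elongation genes had 20 lower of 33 in each line (26 and 22 adjusted over the list alone, medians -2.29 and -2.45, adjusted p = 8.4e-11 and 2.5e-08). Carbon starvation genes had 7 lower of 15 in each (8 adjusted over the list alone in each, medians -1.15 and -0.88, adjusted p = 1.6e-04 and 3.1e-04), with TPS11 at -2.61 ± 0.24 and -2.89 ± 0.24. Root markers had 5 and 6 lower of 15 (7 adjusted over the list alone in each, adjusted p = 9.7e-04 and 5.1e-04). Phenylpropanoid genes had 5 lower with 1 higher and 7 lower of 17 (6 with 1 higher, and 8, adjusted over the list alone, adjusted p = 0.019 and 0.0032). Nitrate uptake and assimilation had 1 and 2 lower of 4 (2 and 3 adjusted over the list alone, adjusted p = 0.015 and 0.017), with the nitrite reductase gene NIR1 at -2.02 ± 0.37 and -1.98 ± 0.37. Early ROS-responsive regulators had 5 and 4 lower and 1 higher of 13 in each (the same adjusted over the list alone, adjusted p = 0.014 and 0.042). Antioxidant enzymes were lower by camera in K87R (8 lower and 2 higher of 20, and 10 and 2 adjusted over the list alone, adjusted p = 0.017).

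Cold and abscisic acid response genes rose, 7 of 10 in each line (7 adjusted over the list alone in each, medians 4.65, or 4.50 with members at their bound, and 4.40, adjusted p = 1.6e-06 and 3.6e-05), RD29A by 6.58 ± 0.53 and 7.06 ± 0.55. Salicylate and jasmonate defence genes rose, 4 of 10 in each (5 and 7 adjusted over the list alone, medians 1.14 and 1.36, adjusted p = 9.7e-04 and 5.1e-04), the jasmonate synthesis gene LOX2 by 1.14 ± 0.24 and 1.397 ± 0.24. Seed storage and late embryo markers rose, 5 and 4 of 6 (6 and 5 adjusted over the list alone, medians 6.83 and 5.15, or 4.03 and 3.58 at the bound, adjusted p = 1.3e-07 and 3.1e-04). Heat shock response genes had 7 higher and 2 lower in K87Q and 9 and 4 in K87R (9 and 2, and 10 and 5, adjusted over the list alone, adjusted p = 0.037 and 0.030). DREB2A, a dehydration and heat response factor gene, rose by 3.65 ± 0.60 and 3.95 ± 0.60. Meristem and cell division markers were higher in K87R, 2 of 8 (4 adjusted over the list alone, adjusted p = 0.047). Clock genes changed both ways in the same libraries, 9 higher and 8 lower of 23 in K87Q and 10 and 9 in K87R, with the same counts adjusted over the list alone (adjusted p = 0.52 and 0.27). COR27 rose by 6.45 ± 0.56 and 6.42 ± 0.56, and TOC1 by 2.73 ± 0.28 and 2.80 ± 0.28.

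Of the genes named for hy5, GLYI4 fell (-1.79 ± 0.29 and -1.90 ± 0.29) and GRP9 rose (2.29 ± 0.56 and 2.21 ± 0.57) in both lines, and BBX16 fell (-3.79 ± 0.28 and -3.03 ± 0.27). LPR1 rose by 3.40 ± 0.72 and 2.54 ± 0.71. MYB12 was higher in K87Q by a ratio of 40.4 (7.01 to 1617, adjusted p = 0.0016) and held 9 counts over the K87R libraries (adjusted p = 0.19). FLS1 was at 0.33 ± 0.50 and -0.84 ± 0.52 (adjusted p = 0.70 and 0.26). 4CL3 was at 0.85 ± 0.52 and 0.49 ± 0.53 (adjusted p = 0.28 and 0.54). PAL1 was at -0.81 ± 0.36 and -0.98 ± 0.36 (adjusted p = 0.13 and 0.059). In K87Q 1488 genes were higher and 1898 lower than in hy5, 3386 in all (10137 with the spread from the 6 libraries, 10442 from the 15 growth-light libraries, 8296 without the high-light replicate 3 libraries, 1995 to 2212 without any one of the 6 libraries). In K87R 2238 were higher and 2288 lower, 4526 in all (11407, 11299 and 9336 by the same fits, and 2866 to 3075 without any one of the 6 libraries).

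The substitutions were compared with the unsubstituted line. COR15B had 0 counts in K87K and was at least 840-fold higher in K87Q and at least 1105-fold higher in K87R. The defensin gene PDF1.2 was at least 161-fold and at least 225-fold higher, LEA7, a late embryogenesis abundant gene, at least 78.8-fold and at least 83.3-fold, and HDA15 by ratios of 754 (135 to 29811) and 1055 (189 to 41709). The beta-glucosidase gene BGLU35 had 0 counts in both substituted lines and was at least 247-fold and at least 194-fold lower, and EXT12 fell (-5.96 ± 0.65 and -6.69 ± 0.68).

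Core clock genes differed from K87K in both lines. Of 23 circadian clock genes 8 were higher and 8 lower in K87Q and 9 and 7 in K87R (11 and 10, and 11 and 8, adjusted over the list alone, medians 0.05 and 0.42, adjusted p = 0.61 and 0.29). COR27 (5.52 ± 0.52 and 5.48 ± 0.52), the evening gene BOA (4.40 ± 0.49 and 4.24 ± 0.49) and its homologue LUX (2.18 ± 0.28 and 2.205 ± 0.28) rose. CCA1, LHY and TOC1 were added after their values were seen. The morning genes CCA1 (-4.80 ± 0.71 in K87Q and -4.04 ± 0.69 in K87R) and LHY (-5.38 ± 0.89 and -3.79 ± 0.81) fell, and TOC1 rose by 1.82 ± 0.27 and 1.90 ± 0.27. CCA1 held 30.1 to 40.4 CPM in K87K, 0.157 to 2.25 in K87Q and 1.24 to 3.22 in K87R.

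**Figure D4:**
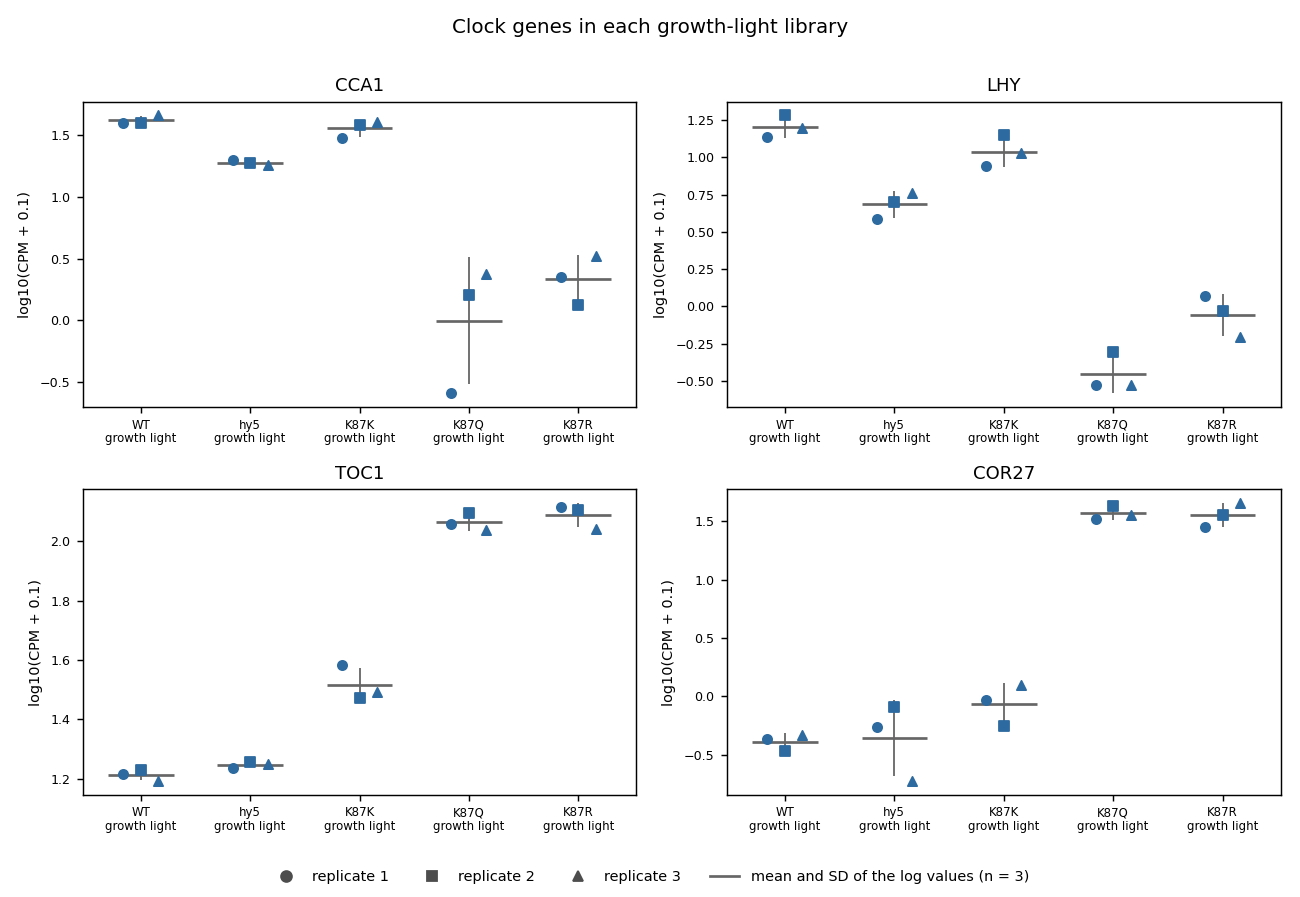
CCA1, LHY, TOC1 and COR27 in the 15 growth-light libraries, as log10 of CPM plus 0.1, by group. Points are libraries, bars the mean and SD of the log values (n = 3). K87Q and K87R lie below every other group for CCA1 and LHY and above every other group for TOC1 and COR27.

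Photosynthesis lists were lower than in K87K in the same libraries. Photoprotection had 10 lower and 1 higher of 24 in K87Q and 15 and 2 in K87R (14 and 1, and 17 and 2, adjusted over the list alone, medians -1.20 and -1.46, adjusted p = 2.6e-06 and 1.1e-07). SIG5 was at -3.58 ± 0.39 and -2.89 ± 0.38 and the zeaxanthin epoxidase gene ZEP at -2.41 ± 0.32 and -2.02 ± 0.31. Chlorophyll biosynthesis had 10 lower and 1 higher, and 11 lower, of 28 (11 and 1, and 13 and 1, adjusted over the list alone, medians -0.71 and -0.95, adjusted p = 1.3e-05 and 6.8e-07). HEMA1 was at -3.64 ± 0.28 and -3.16 ± 0.27 and CHLH, a magnesium chelatase gene, was at -3.21 ± 0.51 and -3.41 ± 0.51. The photosystem list had 7 lower, and 8 lower and 1 higher, of 33 (7, and 9 and 1, adjusted over the list alone, medians -0.92 and -1.28, adjusted p = 2.8e-04 and 6.3e-06). The light-harvesting complex list had 5 and 7 lower of 20 (6 and 9 adjusted over the list alone, medians -1.14 and -1.74, adjusted p = 0.0093 and 1.8e-04), with LHCB2.1 at -3.33 ± 0.83 and -4.26 ± 0.87. HY5-COP1 photomorphogenesis and UV-B genes had 8 and 7 lower of 21 (11 and 10 adjusted over the list alone, medians -1.18 and -0.72, adjusted p = 6.6e-04 and 3.6e-04). BBX25 was at -2.44 ± 0.39 and -2.40 ± 0.39 and BBX24 at -1.55 ± 0.26 and -1.76 ± 0.26.

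Elongation genes had 13 and 11 lower of 33 (25 and 15 adjusted over the list alone, medians -1.95 and -1.48, adjusted p = 2.3e-08 and 6.8e-07), among them PIF5 (-1.45 ± 0.26 and -1.36 ± 0.26) and the auxin synthesis gene YUC8 (-2.51 ± 0.52 and -2.51 ± 0.53). Carbon starvation genes had 9 and 8 lower of 15 (10 and 2 higher, and 10 and 1 higher, adjusted over the list alone, medians -1.74 and -1.68, adjusted p = 1.3e-05 and 6.3e-06), with TPS11 at -3.30 ± 0.24 and -3.58 ± 0.25. Root markers had 5 lower of 15 in each (5 and 6 adjusted over the list alone, medians -1.26 and -1.02, adjusted p = 0.0097 and 0.0018). Phenylpropanoid genes had 6 lower of 17 in each (6 adjusted over the list alone in each, adjusted p = 0.016 and 8.8e-04). Early ROS-responsive regulators had 5 and 4 lower of 13 (5, and 6 with 1 higher, adjusted over the list alone, adjusted p = 0.0093 and 0.015), with the touch gene TCH4 at -4.36 ± 0.43 and -4.58 ± 0.43. In K87R flavonoid biosynthesis (2 lower of 16, and 1 adjusted over the list alone, median -0.75) and flavonoid regulators (3 lower of 11, and 3 adjusted over the list alone, median -1.07) were also lower (adjusted p = 0.028 in each).

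Cold and abscisic acid response genes had 6 higher, and 4 higher and 1 lower, of 10 (7 and 1, and 6 and 1, adjusted over the list alone, medians 2.83 and 2.80, adjusted p = 2.6e-06 and 1.1e-05), with RD29A at 5.16 ± 0.50 and 5.64 ± 0.51. Seed storage and late embryo markers had 5 higher of 6 in each (6 and 5 adjusted over the list alone, medians 6.75 and 5.71, or 5.32 and 4.87 at the bound, adjusted p = 5.9e-09 and 5.0e-06). Salicylate and jasmonate defence had 3 and 4 higher of 10 (3 and 5 adjusted over the list alone, adjusted p = 0.0086 and 0.0015). Heat shock response had 8 higher and 1 lower, and 12 and 2, of 28 (10 and 3, and 12 and 4, adjusted over the list alone, adjusted p = 5.8e-04 and 2.0e-04), and HSFA2 rose by 5.70 ± 0.79 and 5.32 ± 0.78. Lysine acetyltransferases and deacetylases had 5 and 3 higher of 21 (the same adjusted over the list alone, medians 0.31 and 0.27, adjusted p = 0.011 and 0.020). HDA15, all but absent in K87K, was a member, and the list was not tested without it. Besides HDA15, the deacetylase genes HD2D (2.40 ± 0.46 and 2.099 ± 0.45) and HD2A (1.28 ± 0.35 and 1.65 ± 0.35) rose. Meristem and cell division markers were higher in K87R, 2 of 8 (2 adjusted over the list alone, adjusted p = 0.028).

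Against K87K, 1339 genes were higher and 1760 lower in K87Q, 3099 in all (8709 with the spread from the 6 libraries, 10026 from the 15 growth-light libraries, 7916 without the high-light replicate 3 libraries, 1879 to 2139 without any one of the 6 libraries). In K87R 1357 were higher and 1693 lower, 3050 in all (8940, 9937 and 7687 by the same fits, and 1744 to 2009 without any one of the 6 libraries).

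**Figure D5:**
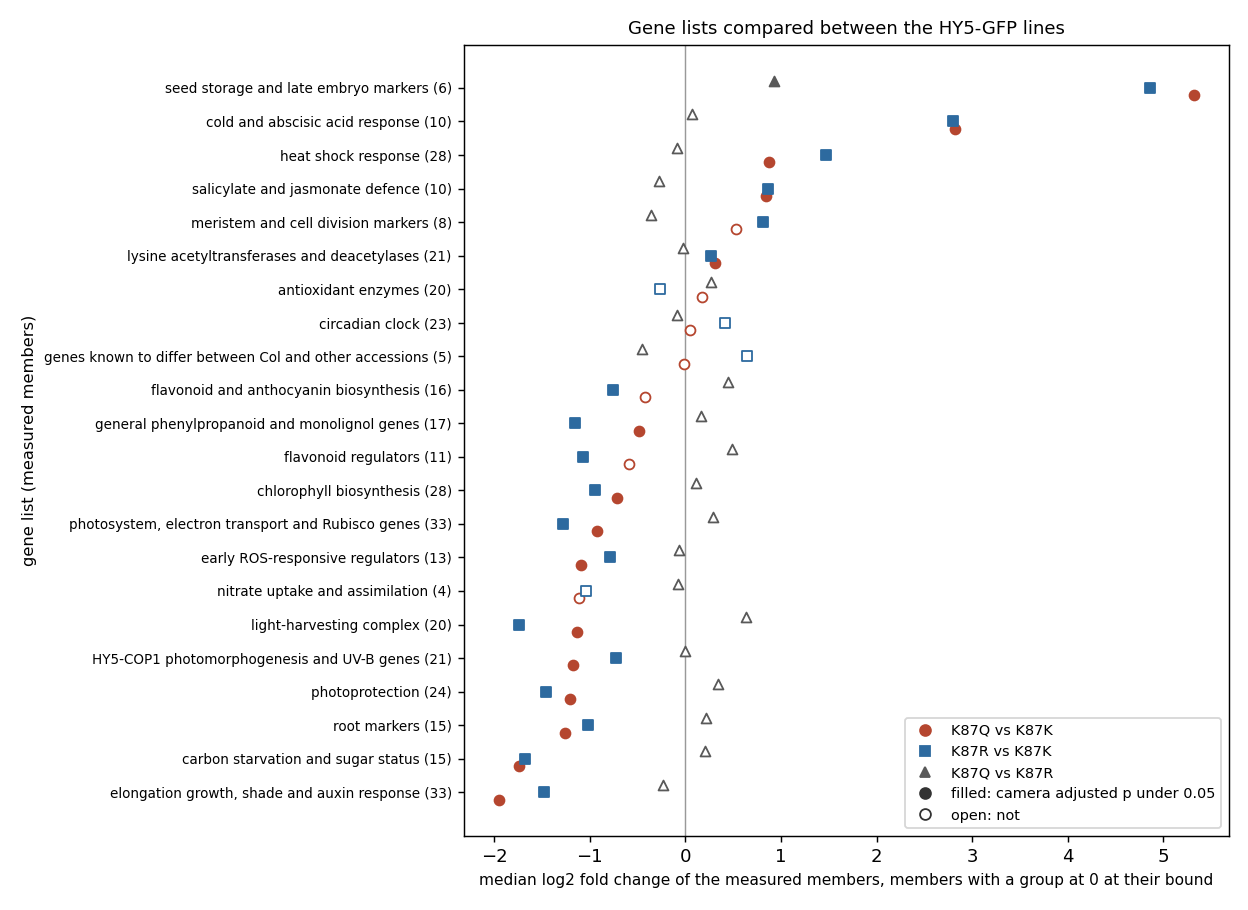
Median log2 fold change of each gene list between the HY5-GFP lines, members with a group at 0 placed at their bound. Filled points passed camera with its preset correlation. Points of K87Q and K87R against K87K lie on the same side of 0 for lists such as elongation growth (-1.95 and -1.48), and 1 list passed between K87Q and K87R.

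K87Q was compared with K87R to ask whether the acetyl-mimicking and the unacetylatable protein differed. By the edgeR fit over 21 libraries 0 genes passed, 1538 genes had an unadjusted p under 0.05, and DESeq2 called 61. Seed storage and late embryo markers were higher in K87Q as a list, with 0 of 6 members called by edgeR (2 adjusted over the list alone, median 0.93, adjusted p = 1.6e-04). CRA1 was at 1.96 ± 0.72 (adjusted p = 0.55) and SESA2 at 3.99 ± 1.32 (adjusted p = 0.55), with all 3 K87Q libraries above all 3 of K87R. MYB12 was at 2.59 ± 0.68 (adjusted p = 0.45). The count was 4436 with the spread from the 6 libraries, 5372 from the 15 growth-light libraries, 2148 without the high-light replicate 3 libraries and 0 without any one of the 6 libraries. On simulated data the fit over 21 libraries found 1% of 2-fold and 48% of 4-fold changes here when the spreads differed by light, so a count of 0 does not show that the lines were alike. The fit of growth-light libraries, with a biological coefficient of variation of 0.189 against 0.431, found the lines to differ in 5372 genes. On simulated data that fit made 11 false calls of 184.

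The genes called between hy5 and WT in high light were followed as sets in the lines, with no library shared. In K87K against hy5, the 466 genes lower in hy5 had a median log2 of 0.20, with 64.4% higher (adjusted p = 7.6e-04), and the 170 higher in hy5 a median of -0.34 (adjusted p = 9.3e-09). With an estimated correlation these were adjusted p = 0.74 and 0.14. Against K87K, the 466 genes had medians of -0.35 in K87Q (adjusted p = 2.4e-04) and -0.55 in K87R (adjusted p = 8.4e-08), each at adjusted p = 0.74 with an estimated correlation. Leaving out 1 library redefined the set, so these fits did not follow the same 466 genes. The K87Q median of the redefined set was between -0.63 and -0.50, further from 0 in each of the 6 fits. The 170 genes had medians of 0.08 and 0.00 against K87K (adjusted p = 0.99 and 0.88). Against hy5 both sets were lower in these lines. The 466 genes had -0.18 in K87Q (adjusted p = 0.067) and -0.30 in K87R (adjusted p = 0.0016), opposite in sign to K87K. The 170 genes had -0.20 in K87Q and -0.12 in K87R, the sign seen in K87K, each at adjusted p = 0.0016. With an estimated correlation none of these 4 passed (adjusted p = 0.91, 0.74, 0.58 and 0.58). In each of the 6 fits that left out 1 library, the higher set as redefined there had medians further from 0, at -0.44 to -0.30 in K87Q and -0.29 to -0.19 in K87R. The lower set, likewise redefined, had medians of -0.32 to -0.20 in K87Q, called in 4 of the 6 fits, and -0.42 to -0.33 in K87R. Between K87Q and K87R the 466 genes had a median of 0.21 (adjusted p = 0.0016, or 0.74 with an estimated correlation). Without the high-light replicate 3 libraries, when the sets held 3348 and 2769 genes, the K87K medians against hy5 were -0.05 and 0.09, the opposite signs, and the higher set had 0.10 in K87Q and 0.20 in K87R against hy5 (adjusted p = 0.91 and 0.36). The lower set then had 0.02 in K87Q (adjusted p = 0.46) and -0.21 in K87R (adjusted p = 0.0030) against hy5. It had medians of 0.03 in K87Q against K87K (adjusted p = 0.91), -0.17 in K87R against K87K (adjusted p = 0.0075) and 0.24 between K87Q and K87R (adjusted p = 4.2e-07).

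Genes called in the WT light response were also followed. The 2191 that fell in WT were lower than in K87K in K87Q (median -0.47, adjusted p = 3.4e-07) and K87R (-0.49, adjusted p = 1.6e-08), and the 2828 that rose were higher (0.24, adjusted p = 4.7e-04, and 0.28, adjusted p = 3.4e-04). These held with an estimated correlation (adjusted p = 0.0028, 0.0021, 0.0068 and 0.0068). Sets redefined without the high-light replicate 3 libraries gave -0.31 and 0.27 in K87Q (adjusted p = 1.3e-05 and 2.9e-05) and smaller medians of -0.20 and 0.15 in K87R (adjusted p = 4.0e-04 and 0.025). Between K87Q and K87R the medians were 0.03 and -0.02 (adjusted p = 0.34 and 0.81). Without the high-light replicate 3 libraries, which redefined the sets, they were -0.07 (adjusted p = 0.084) and 0.15, the latter called (adjusted p = 4.4e-04).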

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

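The tests chosen only after the result was seen were the heat-shock level and the shared deviation of the replicate 3 libraries, the HY5 level for the differences from K87K, all 3 tests of HDA15 in K87K, and the count of interaction splits that part like-numbered pairs.

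The light response differed between hy5 and WT by the interaction test in 18 genes. For those with a symbol the log2 difference (hy5 minus WT) was 3.49 for BBX16 (adjusted p = 9.4e-05), 2.52 for ACS6 (adjusted p = 0.035), 1.98 for BGLU18 (adjusted p = 0.017), -2.18 for HCF152 (adjusted p = 0.035), -3.71 for UMAMIT33 (adjusted p = 0.025), -3.72 for RWP1 (adjusted p = 0.0012), -3.88 for FLS1 (adjusted p = 0.035), -4.18 for NRT1.8 (adjusted p = 0.035) and -5.47 for 4CL3 (adjusted p = 0.017). JAZ7 (-7.98, adjusted p = 0.023), CKX5 (-7.87, adjusted p = 0.017), GA2OX4 (-7.35, adjusted p = 0.033) and CYCP3;2 (-6.59, adjusted p = 0.033) fell outside the rule for naming genes and were chosen after their values were seen. With the spread taken from these 12 libraries alone, 1 gene (BBX16) passed. Chance was not excluded for this count: 49 of 100 splits drawn of these 12 libraries gave at least as many genes, and the highest other gave 4087, far above the real 18, which points to a structure of the samples such as that of replicate 3. Of the 42 drawn splits that parted all 3 like-numbered pairs in high light, as the real one does, 24 gave at least as many genes and the highest other gave 726. That split left growth light as it was and exchanged the genotypes of high-light replicates 1 and 2.

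In both genotypes the high-light replicate 3 library lay apart from replicates 1 and 2. The tables argue against a treatment missed altogether, since the median heat-shock gene in replicate 3 was 599.9-fold of growth light in hy5 and 1121-fold in WT. Heat-shock genes cannot show that the full light dose was given, which stays open. In WT, HYH held 13.4 CPM in replicate 3 against 33.8 and 26.2 in replicates 1 and 2, and HY5 held 41.9 against 106 and 51.9. In hy5, HYH held 11.4 against 13.4 and 14.8. Shared handling of the replicate 3 seedlings may explain the separation: the deviations of the 2 replicate 3 libraries correlated at r = 0.483 across genes, which are not independent replicates. The gene length test could not decide on RNA degradation. Gene length followed the deviation with rho = 0.340 in WT and 0.137 in hy5, longer genes being relatively higher in replicate 3. Replicate 1 against 2 in WT gave -0.388. The test asked for a large rho of one sign in both genotypes and did not say which sign, so it cannot show that replicate 3 was the degraded one. The design names no biological difference between replicates, so none was tested.

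K87Q and K87R each differed from K87K in many genes (3099 and 3050), clock genes included, while 0 genes passed between them by edgeR (61 by DESeq2, 1538 at an unadjusted p under 0.05), though 4436 did with the spread from their 6 libraries, 5372 with growth-light libraries alone and 2148 without the high-light replicate 3 libraries. The tables argue against the HY5 transcript level, which differed from K87K by at most 0.275 on the log2 scale with scaled libraries. Without scaling, HY5 held 278 CPM in K87K, 309.8 in K87Q and 528 in K87R. Loss of HDA15 in K87K as the whole cause stays open. If HDA15 acted alike at any HY5 level, its loss would place WT as far from K87K as K87Q. The median ratio was 0.176 (quartiles -0.06 to 0.40, 2070 genes called in both). That argues against this case only, since WT held 8.64 CPM of HY5 and K87K 284. Harvest at another time of day may contribute, though its 6 marker genes were mixed. The median log2 change of 3 evening genes exceeded that of 3 morning genes by 1.42 in K87R and 2.11 in K87Q. The evening gene GRP7 was higher (4.27 ± 0.79 and 4.92 ± 0.82), but the morning gene RVE2 was higher too (2.68 ± 0.49 and 2.09 ± 0.48). RVE2 lay above the evening genes GRP8 and CAT3 in both lines. The medians were those of GRP8 and of the morning genes RVE3 (K87Q) or RVE7 (K87R). GRP8, CAT3, RVE3 and RVE7 passed in neither line (adjusted p from 0.114 to 0.844). The substitution itself, an effect of the insertion in each line, and for K87R the other hy5 allele, stay open and untested.

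HDA15 held 1 count over the 3 K87K libraries against 864 in WT, 0.128% of the WT level. The tables argue against deletion of a wider segment, since the lowest of the 10 expressed neighbours was at 50.2% of its level in the other growth-light groups. Repression by abundant HY5 stays open: HDA15 was at 95.2% of WT in K87Q and 142% in K87R, but both hold a substituted HY5, and no group besides K87K holds the unsubstituted protein from a constitutive promoter. A lesion within HDA15 in this line may also explain it, with the upper counting limit at 0.711% of WT, but this cannot be told from a count per gene, which cannot place a lesion. Whether it arose with the transgene was not tested.

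A comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For 9 comparisons 1 of the 10 splits, the real one, gave as many genes, and the highest other gave 0. The real counts were 5019 (WT high against growth light), 7390 (hy5 high against growth light), 44 (hy5 against WT in growth light), 170 (K87K against hy5), 3386 (K87Q against hy5), 4526 (K87R against hy5), 3099 (K87Q against K87K), 3050 (K87R against K87K) and 221 (K87K against WT). For K87Q against K87R all 10 splits gave 0.

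For hy5 against WT in high light 5 of 10 splits gave at least the real 636, and the highest other gave 5188. The 4 splits that put the replicate 3 libraries of WT and hy5 in one group gave 5188, 4824, 2048 and 23 genes, so 3 of them point to that structure and 1 does not. Of the 4 splits that part every pair of like-numbered libraries, the real one gave 636 and the others 1834, 19 and 0, and the split with 1834 differs from the real one by exchanging the replicate 3 libraries. With the replicate number as a block, the 6 libraries gave 29 genes.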

How the results depend on the processing

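The alternatives added after seeing the data were the fit without the high-light replicate 3 libraries, the fit of growth-light libraries alone, the fit of the 6 high-light libraries with a block, and the estimated inter-gene correlation for the sets of hy5-dependent and light-responsive genes. Every alternative chosen before the data were examined was run. For named genes and lists, directions were steadier than call counts. The counts rested on the spread pooled over 21 libraries: the biological coefficient of variation was 0.431, against 0.245 without the high-light replicate 3 libraries and 0.189 in growth light alone. Of the alternatives for named genes, 3998 held direction and side of the threshold, 306 lost the call, 29 gained it and 2 reversed. For single gene lists the numbers were 366, 80, 3 and 0, and 74 of the 80 came from the estimated correlation. Many of these genes and lists were picked because they were called with all libraries, the genes also for large changes and separated libraries. Few reversals among them therefore say little about other genes. The minimum fold change could reverse no direction, since it used the same fold changes. Median-ratio scaling changed the side of the threshold for no named gene or list. The cause was not tested for any change below except where fewer libraries or another pooled spread is part of the alternative. Library totals ran from 7283290 to 22101539 counts, so genes near the filter were measured least well in the smallest library.

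With only the groups compared in the fit, the called genes numbered 2906 (WT, high against growth light), 3097 (hy5, high against growth light), 1 (interaction), 6863 (hy5 against WT, growth light), 1 (hy5 against WT, high light), 5497 (K87K against hy5), 10137 (K87Q against hy5), 11407 (K87R against hy5), 8709 (K87Q against K87K), 8940 (K87R against K87K), 4436 (K87Q against K87R) and 5049 (K87K against WT). With growth-light libraries alone they numbered 4618 (hy5 against WT), 5497 (K87K against hy5), 10442 (K87Q against hy5), 11299 (K87R against hy5), 10026 (K87Q against K87K), 9937 (K87R against K87K), 5372 (K87Q against K87R) and 5036 (K87K against WT). By DESeq2 they numbered 361 (interaction), 346 and 1653 (hy5 against WT in growth and high light), 605 (K87K against hy5), 61 (K87Q against K87R) and 753 (K87K against WT).

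Without the high-light replicate 3 libraries the counts were 9513 (WT, high against growth light), 5153 (interaction), 2125 and 6117 (hy5 against WT in growth and high light), 2956 (K87K against hy5), 8296 (K87Q against hy5), 9336 (K87R against hy5), 7916 (K87Q against K87K), 7687 (K87R against K87K), 2148 (K87Q against K87R) and 2740 (K87K against WT), and genes lower in both light responses numbered 2650. This fit redefined the sets of genes lower or higher in hy5 under high light. Their median log2 changes were then -0.0473 and 0.0922 (lower and higher set, K87K against hy5), 0.0983 and 0.204 (higher set, K87Q and K87R against hy5), 0.0332 (lower set, K87Q against K87K), 0.0375 (higher set, K87R against K87K) and -0.110 (higher set, K87Q against K87R, called at adjusted p = 0.020). For the light-responsive sets, K87Q against K87R gave -0.0745 (lower) and 0.154 (higher, called at adjusted p = 4.4e-04). Gene lists called numbered 8 (WT, high against growth light, where 2 of the 5 with all libraries, the clock and the root markers, were lost), 8 (hy5 against WT, growth light), 4 (K87K against hy5) and 5 (K87Q against K87R).

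With the estimated correlation the medians were unchanged by construction, but these sets lost their call: 0.202 and -0.337 (lower and higher set, K87K against hy5), -0.201 (higher set, K87Q against hy5), -0.300 and -0.122 (lower and higher set, K87R against hy5), and -0.350, -0.547 and 0.209 (lower set, for K87Q against K87K, K87R against K87K and K87Q against K87R). Gene lists called fell to 1 and 2 (WT and hy5, high against growth light), 0 (interaction), 0 and 0 (hy5 against WT in growth and high light), 6 (K87Q against hy5), 6 (K87R against hy5), 4 (K87Q against K87K), 6 (K87R against K87K), 0 (K87Q against K87R) and 1 (K87K against WT).

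The lower set in K87Q against hy5 became called with no filter on low counts (-0.221), with sets limited to an absolute log2 change of at least 1 (-0.230) and with the replicate block (-0.234). Every alternative for the sets in this paragraph redefined them. For the higher set, never called in these fits, the direction given by camera reversed with no filter in K87Q against K87R (-0.0657), and with the limited sets in K87Q against K87K (0.109), K87R against K87K (0.0408) and K87Q against K87R (-0.0258), while the medians held the sign they had with all 21 libraries (-0.0141 for K87Q against K87R, 0.0831 for K87Q against K87K and 0.0039 for K87R against K87K). Other alternatives changed the sign of medians, with no call in either fit: median-ratio scaling in all 3 (0.0013, -0.0065 and -0.0211), no filter in K87Q against K87K (-0.0205), the block in K87Q and K87R against K87K (-0.0095 and -0.0460), and the fit without the high-light replicate 3 libraries in K87Q against K87K (-0.0680). The replicate block gave 1 called list for K87K against hy5, and in the 6 high-light libraries alone the block gave 29 genes for hy5 against WT. Without scaling of library sizes HY5 held 309.8 CPM in K87Q and 528 in K87R, against 278 in K87K.

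Leaving out 1 library at a time gave 2 to 3382 genes for the interaction, with 3382 without WT high-light replicate 3 and 1174 without hy5 high-light replicate 1. The range was 3 to 10 for hy5 against WT in growth light and 237 to 4737 in high light, with 4737 without WT high-light replicate 3. It was 37 to 57 for K87K against hy5, 1995 to 2212 for K87Q against hy5, 2866 to 3075 for K87R against hy5, 1879 to 2139 for K87Q against K87K, 1744 to 2009 for K87R against K87K and 42 to 73 for K87K against WT. Each of these fits also redefined the sets of genes lower or higher in hy5 under high light. The median was -0.318 to -0.205 for the lower set in K87Q against hy5, called without hy5 growth-light replicate 3 (adjusted p = 0.044) and without K87Q replicates 1, 2 and 3 (adjusted p = 0.0088, 0.010 and 0.0051), and -0.108 to -0.0516 for the higher set in K87Q against K87R. The higher-set median was -0.119 to -0.0298 in K87Q against K87K, below 0 in each such fit, and -0.0090 to 0.0880 in K87R against K87K. The log2 change of HY5, called in neither, ran from -1.37 to 0.69 (hy5, high against growth light) and from -0.38 to 0.00054 (K87Q against K87K), reversing without hy5 growth-light replicate 3 and without K87K growth-light replicate 3.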

Other observations

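The genes below were chosen after their values were seen, no explanation was tested for them, and levels are means ± SD in CPM over 3 growth-light libraries. HYH, a homologue of HY5, held 9.63 ± 1.60 in WT and 7.87 ± 1.21 in hy5. It was lower than in hy5 in K87Q (log2 -1.71 ± 0.34, adjusted p = 0.0018) and in K87R (-2.31 ± 0.355, adjusted p = 1.5e-04), with every library of each line below every hy5 library. The K87K libraries, at 5.88, 3.68 and 3.93, also lay below every hy5 library (6.52, 8.86 and 8.22). RUP1 held 61.5 ± 4.66 in WT, 88.3 ± 3.09 in hy5 and 44.0 ± 10.9 in K87K, against 5.38 ± 3.46 in K87Q and 2.09 ± 0.277 in K87R.

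CYP79F1, a glucosinolate gene, held 29.6 ± 3.83 in WT, 5.69 ± 2.05 in hy5, 0.453 ± 0.205 in K87K, 6.59 ± 0.879 in K87Q and 10.5 ± 1.59 in K87R. It was higher than in K87K by log2 3.84 ± 0.50 in K87Q (adjusted p = 3.3e-05) and 4.51 ± 0.51 in K87R (adjusted p = 7.3e-06), with every library of each line above every K87K library. ESM1 held 127 ± 3.80 in K87K and 126 ± 3.57 in K87Q, against 54.8 ± 1.56 in K87R, 35.1 ± 0.369 in WT and 26.7 ± 1.29 in hy5. BSU1 was higher in K87K, K87Q and K87R (30.7 ± 7.98, 18.7 ± 2.31 and 13.0 ± 1.63) than in hy5 (2.08 ± 0.501) in 3 of 3 libraries each, with adjusted p = 1.5e-04, adjusted p = 6.1e-05 and adjusted p = 2.6e-04. The called changes of HYH, CYP79F1 and BSU1 given here held their direction and their call under every alternative run.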
